A study of Drosophila melanogaster with 4 samples.

How the data were processed

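The measurements are 4 two-colour tiling arrays of genomic DNA from Kc167, a female cell line derived from Drosophila melanogaster embryos. Per the labels' protocols, cells grown at 25 °C received 1 mM hydroxyurea for 3 hours, then 50 ug/ml of BrdU, and were harvested 20 hours later, and BrdU-containing DNA was precipitated with an antibody. Hydroxyurea lowers the supply of DNA precursors, so that forks from origins firing early in S phase stall and later origins stay unfired. BrdU, a thymidine analogue, marks the DNA made meanwhile. All 4 arrays carry the same group label, replicates 1 to 4, so no comparison between groups was possible and each ratio was set against the median of its own array. The labels name separate arrays and DNA extractions and do not say that these came from separate cultures, so p-values measure the spread between these samples, which may be technical.

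The deposited scanner files hold spot intensity in the Cy3 and Cy5 channels, and per the file headers they were made with Agilent Feature Extraction 9.5.1.1. Per the file headers, the processed intensity was background-subtracted, detrended across the array and dye-normalized with linear factors and no lowess. The authors' deposited normalized values are a score per probe whose SD over each array was 1.00, so they are in units of that spread and not in plain log2. Their medians were 0.124, 0.155, 0.0529 and 0.0497 for replicates 1 to 4, and their sign followed Cy5 over Cy3, with correlations of 0.952, 0.735, 0.724 and 0.705 across probes with the scanner ratios of the same arrays. How they were centred is not given in the sources used here. The deposited peak list gives 630 regions with a score each, from 30.01 to 3000, and MA2C is named in its source field. The scale of that score and the settings behind it are not given in the sources used here. It was made by the authors from this series, so the array values inside peaks describe the list and are not independent evidence for it. Probe positions are tagged FlyBase release 5.1 and the peak list 5.3, per the file headers, and both are given here as release 5, counted from 1. The gene table at hand is of a later assembly, so no gene was placed on these coordinates. The planned tests of 16 gene lists, of transcription starts inside peaks and of named genes were not run, and regions are named by position.

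Each array held 241469 probes of 45 to 60 bases after control spots were left out, at a median spacing of 470 bases on the 5 large arms. Between 106 and 359 probes per array carried an outlier flag and were left out on that array. Between 99.0% and 99.8% of probes were well above background in each channel of each array. The number of arrays limits the precision of each value.

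Log2 of Cy5 over Cy3 from the processed signals was centred on the median of each array. Ratios were then turned by the dye labels as channel 2 over channel 1, with channel 1 in Cy3 on replicates 1 and 3 and in Cy5 on replicates 2 and 4. The labels do not say which channel held the precipitated DNA, or what the other channel held. The overall sign was taken from the direction in which the deposited peaks ran, and is therefore only likely. Below, the channel in the denominator of the ratio with replicate 2 turned is called the reference channel. Replicate 2 ran against its dye label, so the comparisons are given with the signs as labelled and with replicate 2 turned, and a value given in one orientation alone is named as such. The turned version was chosen after seeing the data, and the version as labelled was fixed before the data were examined. With replicate 2 turned, the numerator is Cy5 on replicates 1, 2 and 3 and Cy3 on replicate 4. A dye effect therefore does not cancel in the mean of the turned version.

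Probes were averaged in 10 kb windows with at least 5 probes, which left 12094 windows, and in deposited peaks with at least 3 probes. Windows and peaks were tested against 0 with limma 3.58.1 in R 4.3.3 (an intercept alone, moderated variances, two-sided, Benjamini-Hochberg adjusted p under 0.05), peaks together with the windows outside them. Differences per array (inside minus outside peaks, X minus autosomes and, added later, chromosome 4 minus autosomes) were tested by exact permutation of the signs of the 4 arrays, two-sided, in which at least 2 of the 16 assignments are always as large, with Benjamini-Hochberg adjustment over the 3 differences. The share of windows touching a peak was compared between chromosomes by 10000 circular rotations of the peaks along the concatenated arms, two-sided, with Python 3.11.15 and numpy 2.4.6. The X test was planned and the tests of the other 5 arms were added. Named regions are the 12 peaks with the highest mean among those past the threshold and above 0 on all 4 arrays, and the 6 lowest windows past the threshold and below 0 on all 4 arrays, at most 1 per 200 kb. The rule was written for genes nearest to these regions and was applied to the regions alone.

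On simulated windows with the spread of the real arrays, 200 of the 12094 were shifted. With all signs right, limma called 73.0% of the windows shifted by 0.5 and 95.0% of those shifted by 1, with 11 false calls, and with 1 array turned it called none of the shifted windows. In the rotation test of X against autosomes, 5.00% of 200 shifted copies of the peak map gave a p under 0.05. Copies and null were rotations of the same map, so a share near this follows from the construction and is no check of the test. Alternatives were the deposited normalized values, normexp background correction with an offset of 50, loess within arrays, a dye term, a filter on dim and saturated probes, correction for probe GC content, windows of 5 and 20 kb, at least 10 probes per window, an effect size of 0.5, the better-scoring peaks alone, a 50% overlap and leaving out each replicate.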

Results

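Origins that fire early in S phase were mapped in Kc167 cells by BrdU incorporation under hydroxyurea and hybridization to 4 genomic tiling arrays. The deposited peaks covered 17.8 Mb in 630 regions, with a median width of 21.0 kb (interquartile range 15.2 to 31.7 kb). Median spot signals of replicates 1 to 4 were 334, 136, 248 and 450 in Cy3 and 660, 446, 184 and 192 in Cy5. Local background medians lay between 38.0 and 42.0 in Cy3 and between 69.0 and 76.0 in Cy5.

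The direction of the ratios was not settled by the labels. In deposited peaks, Cy5 over Cy3 exceeded the rest of the array by 1.01, 0.90 and 0.83 log2 on replicates 1, 2 and 3, and was -0.46 on replicate 4. Replicates 2 and 4 carry the same dye orientation, yet their ratios correlated at r = -0.51 over all probes and -0.80 over 10 kb windows. Replicates 1 and 2 carry opposite orientations and correlated at 0.96 over windows. These correlations are across probes or windows, which are not independent replicates. Values are therefore given with signs as labelled and with replicate 2 turned, an orientation chosen after seeing the data. That orientation was picked because the arrays then run the same way, so counts, signs and tests made with it are no independent evidence of agreement between arrays.

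The first question was how the early-replicating peaks are spread over the chromosomes, which was taken from the deposited list. The orientation the authors used in calling it is not given in the sources used here. Chromosome 4, the small and largely heterochromatic autosome, stood apart, with 19 peaks over 62.1% of its tiled length, or 15.6 peaks per Mb. The large arms held 96 peaks on 2L (12.1% of the tiled length), 134 on 2R (15.9%), 126 on 3L (16.0%), 118 on 3R (11.8%) and 115 on X (15.3%). Of 10 kb windows, 70.5% touched a peak on chromosome 4 and 18.7% on 2L, 2R, 3L and 3R together. That difference of 51.8 percentage points had a permutation p of 0.00150 by rotation (0.00900 after adjustment over 6 arms), in a test added after the data were seen. On X, 20.8% of windows touched a peak, a difference of 2.10 points from the autosomes that rotation did not separate from 0 (permutation p = 0.487, adjusted p = 0.487). The 3R arm had the lowest share of the large arms, 16.0% against 20.0% on the others, which did not pass either (permutation p = 0.177, adjusted p = 0.470). Contig sets of unplaced or heterochromatic sequence held 2 peaks on 2RHet, 7 on 3LHet, 4 on 3RHet, 6 on U, 3 on YHet and none on 2LHet and XHet.

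Signal in these peaks was compared with the rest of the genome on each array. With replicate 2 turned, probes inside peaks exceeded those outside by 0.80 ± 0.24 log2 (SD, n = 4), or 1.74-fold, and the difference was above 0 on 4 of 4 arrays. In the exact permutation test, 2 of the 16 sign assignments gave a difference as large, the fewest possible, so that this design cannot reach a p under 0.05. As labelled it was 0.35 ± 0.86 (SD, n = 4), above 0 on 3 of 4 arrays, and 0.13, 0.77, 0.19 and 0.31 without replicates 1, 2, 3 and 4 in turn (exact permutation p = 0.5, adjusted p = 0.5 over 3 comparisons). Inside peaks the turned mean was 0.73 ± 0.24 and outside it was -0.07 ± 0.01, against 0.31 ± 0.80 and -0.04 ± 0.06 as labelled. On the large arms the signal fell away quickly beyond the peak edges. The turned mean was 0.13 ± 0.08 within 5 kb of an edge, 0.04 ± 0.06 at 5 to 10 kb and -0.02 ± 0.03 at 10 to 20 kb. It was -0.12 ± 0.02 at 50 to 100 kb and fell no further beyond 100 kb, at -0.10 ± 0.01. As labelled the same distances gave 0.03 ± 0.17, -0.003 ± 0.07, -0.03 ± 0.02, -0.07 ± 0.12 and -0.05 ± 0.09.

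**Figure D1:**
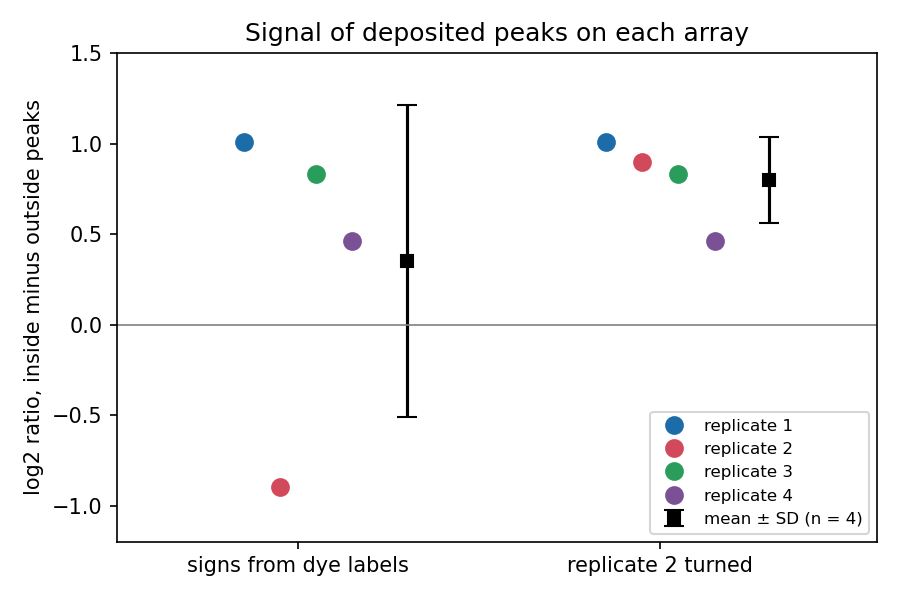
Difference of mean log2 ratio between probes inside and outside deposited peaks (vertical axis) on each array, for signs from the dye labels and with replicate 2 turned; squares are means and bars 1 SD over 4 arrays. Replicate 2 lies at -0.90 as labelled and at 0.90 when turned, while replicates 1, 3 and 4 lie at 1.01, 0.83 and 0.46.

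**Figure D2:**
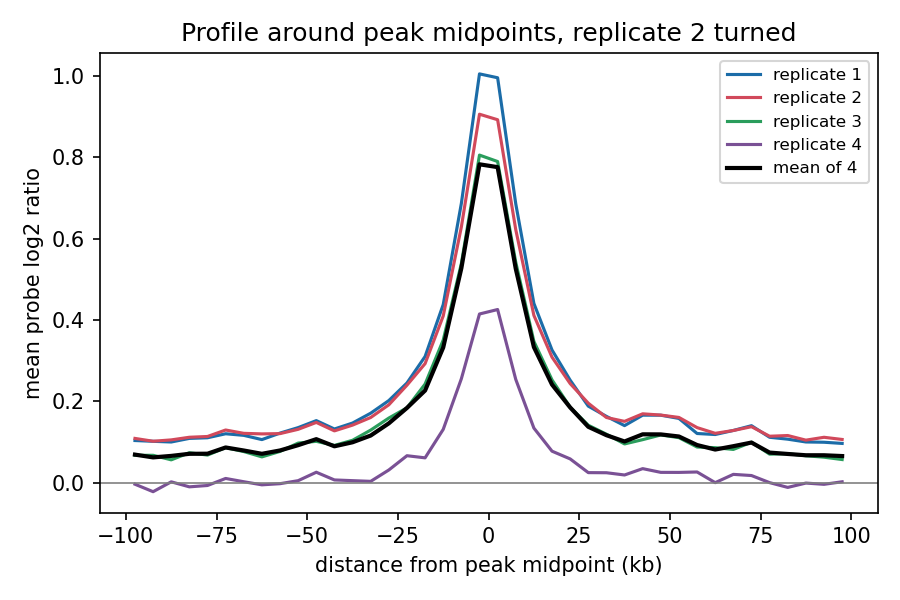
Mean probe log2 ratio (vertical axis) in 5 kb steps from the midpoints of the deposited peaks (horizontal axis, kb) on each array with replicate 2 turned, and the mean of 4 arrays. The mean is 0.78 just beside the midpoint and 0.07 at 97.5 kb from it. Probes that far from a midpoint can lie in or near another peak, so this value does not show how far the signal of a peak reaches. By distance from peak edges on the large arms, the mean was -0.12 ± 0.02 at 50 to 100 kb.

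Tested one by one with limma, 623 of the 630 peaks passed the threshold above 0 with replicate 2 turned, and 601 were above 0 on all 4 arrays. As labelled, limma called no peak, and no peak was above 0 on all 4 arrays. With replicate 2 left out, 609 peaks passed on the 3 arrays whose labels and signals run the same way. The median of the peak means was 0.57 with replicate 2 turned. Of the 7 peaks not called, 3 were all those of YHet and the others lay singly on 2L, 2R, U and X.

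The peaks with the highest turned means were spread over U, X, 3L, 2R and 2L. The highest was U 5282551 to 5308300, at 2.93 ± 0.64 (1.36 ± 3.07 as labelled). In the reference channel this peak was also the brightest of the list, at 23.6 times the autosomal level. Levels of different probes also differ in affinity, and copy number was not tested. The rank of this peak is therefore not read as early firing. Of its 33 probes, 21, 19 and 3 were saturated in Cy5 on replicates 1, 2 and 3 and 9 in Cy3 on replicate 4, each time in the numerator of the turned ratio, so this mean is capped by the scanner and is no exact measure of the peak. X 3229111 to 3373535 followed at 1.49 ± 0.38 (0.64 ± 1.59 as labelled), then 3L 8635551 to 8731738 at 1.46 ± 0.45 (0.65 ± 1.57 as labelled). The widest peak of the list, 266 kb at 3L 11183861 to 11450248, had 1.30 ± 0.35 (0.56 ± 1.40 as labelled). On X, 12599671 to 12673180 had a turned mean of 1.27 ± 0.53, 5762981 to 5817586 of 1.21 ± 0.35 and 16777901 to 16818115 of 1.19 ± 0.30. On 3L, 17892771 to 17952655 had 1.26 ± 0.34, 3366911 to 3492028 had 1.20 ± 0.37 and 7829581 to 7883299 had 1.12 ± 0.30. The remaining 2 were 2R 8856881 to 8944084 at 1.15 ± 0.33 and 2L 16499671 to 16608380 at 1.14 ± 0.29. As labelled, these last 8 peaks had means between 0.49 and 0.58, with SDs between 1.20 and 1.41. Limma's adjusted p for these 12 peaks lay between 0.000769 and 0.00115, against 0.897 as labelled.

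Across the genome, 2979 of 12094 windows (24.6%) were enriched and 3553 (29.4%) depleted with replicate 2 turned. Both words are relative to the median of each array, so depleted means below that median and is no measure of lost BrdU. Only 6 of the depleted windows had a mean of at most -0.5. As labelled, limma called 0 windows enriched and 0 depleted, and 26 windows had an unadjusted p under 0.05, against 7360 with replicate 2 turned. Without replicate 2 the counts were 1952 enriched and 1234 depleted. As labelled, all 4 arrays were above 0 in 94 windows and below 0 in 209, and with replicate 2 turned in 3216 and 4470. With replicate 2 turned, of the enriched windows 1937 (65.0%) touched a deposited peak, and of the depleted windows 3550 of 3553 did not. By arm, with replicate 2 turned, enriched windows made up 23.1% of 2L, 25.8% of 2R, 26.0% of 3L, 18.5% of 3R and 25.1% of X. Depleted windows made up 25.4% of 2L, 32.3% of 2R, 30.9% of 3L, 39.5% of 3R and 22.0% of X. With normexp background correction the depleted windows fell to 684 and the enriched to 2268, and without replicate 1 to 1122 and 1924.

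The lowest windows were on all the large arms. With replicate 2 turned, 3R 7750001 to 7760000 had -0.54 ± 0.25 and 3R 27340001 to 27350000 had -0.54 ± 0.13. The windows 2L 6510001 to 6520000, 2R 3240001 to 3250000, X 720001 to 730000 and 3L 16890001 to 16900000 had -0.52 ± 0.18, -0.51 ± 0.15, -0.50 ± 0.07 and -0.49 ± 0.09. The X window rests on 5 probes, the fewest allowed, and the other named windows on 13 to 21. As labelled these 6 windows had means between -0.31 and -0.20, none of which passed limma's threshold (adjusted p = 0.887). With normexp background correction and replicate 2 turned, 3R 27340001 had -0.23 ± 0.47, X 720001 had -0.23 ± 0.27 and 3L 16890001 had -0.36 ± 0.27.

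X, present without a Y in a female line, was compared with the large autosomal arms. The mean window ratio on X exceeded that on 2L, 2R, 3L and 3R by 0.05 ± 0.04 with replicate 2 turned (SD, n = 4), with 0.07, 0.03, 0.08 and 0.0006 on replicates 1 to 4 (2 of 16 sign assignments as large in the exact permutation test, the fewest possible). As labelled it was 0.03 ± 0.06, and 0.02, 0.05, 0.01 and 0.04 without replicates 1, 2, 3 and 4 in turn (exact permutation p = 0.375, adjusted p = 0.5). A difference of this size is close to the spread between arrays.

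Chromosome 4 exceeded those autosomes by 0.54 ± 0.11 log2 with replicate 2 turned (SD, n = 4), or 1.45-fold, with 0.68, 0.57, 0.44 and 0.46 on replicates 1 to 4 (2 of 16 sign assignments as large in the exact permutation test, the fewest possible). As labelled it was 0.25 ± 0.56, and 0.11, 0.53, 0.19 and 0.18 without replicates 1, 2, 3 and 4 in turn (exact permutation p = 0.5, adjusted p = 0.5). This comparison was added after seeing the data. With replicate 2 turned, 106 of its 122 windows were enriched and 2 depleted, and all of its 19 peaks passed the threshold. Among the contig sets, enriched windows made up 67.6% of 3RHet and 57.0% of U. Their turned means were 0.27 ± 0.09 and 0.36 ± 0.26, and their means as labelled 0.19 ± 0.23 and 0.28 ± 0.37. On 2LHet, 2RHet, 3LHet and XHet, enriched windows made up 28.6%, 27.9%, 31.6% and 18.2%. Their turned means were 0.07 ± 0.12, 0.08 ± 0.11, 0.11 ± 0.09 and 0.08 ± 0.12, with replicate 2 below 0 on each. As labelled they were 0.10 ± 0.09, 0.12 ± 0.04, 0.12 ± 0.07 and 0.12 ± 0.07, with all 4 arrays above 0.

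**Figure D3:**
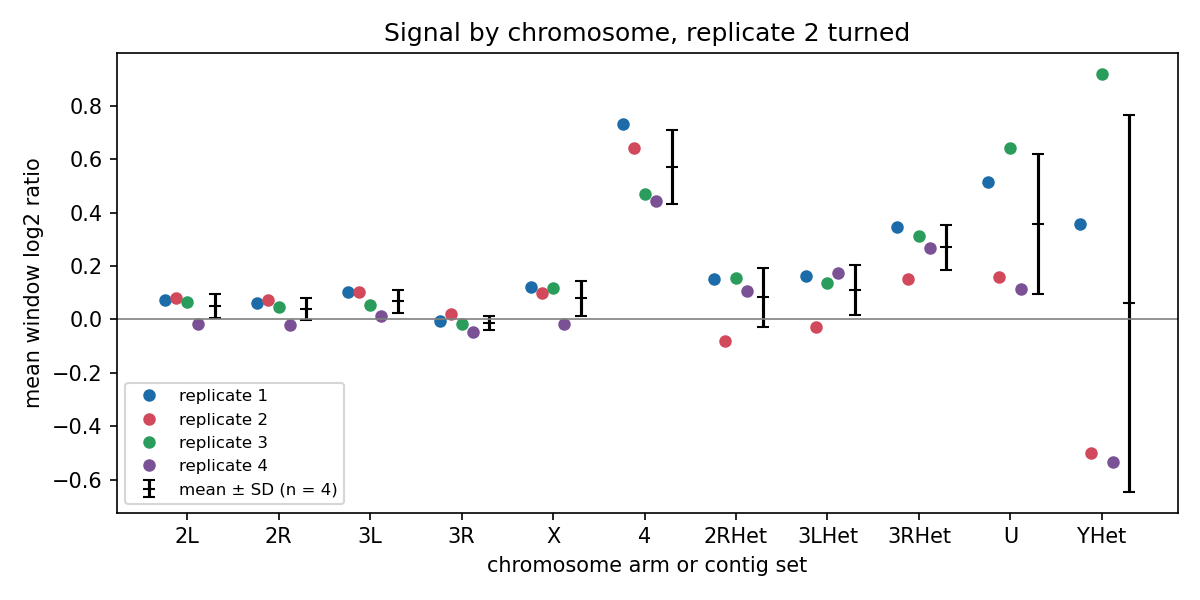
Mean log2 ratio of 10 kb windows (vertical axis) by chromosome arm or contig set (horizontal axis) on each array with replicate 2 turned; bars are the mean ± 1 SD over 4 arrays. Chromosome 4 lies between 0.44 and 0.73 on all arrays, and YHet spreads from -0.53 to 0.92.

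**Figure D4:**
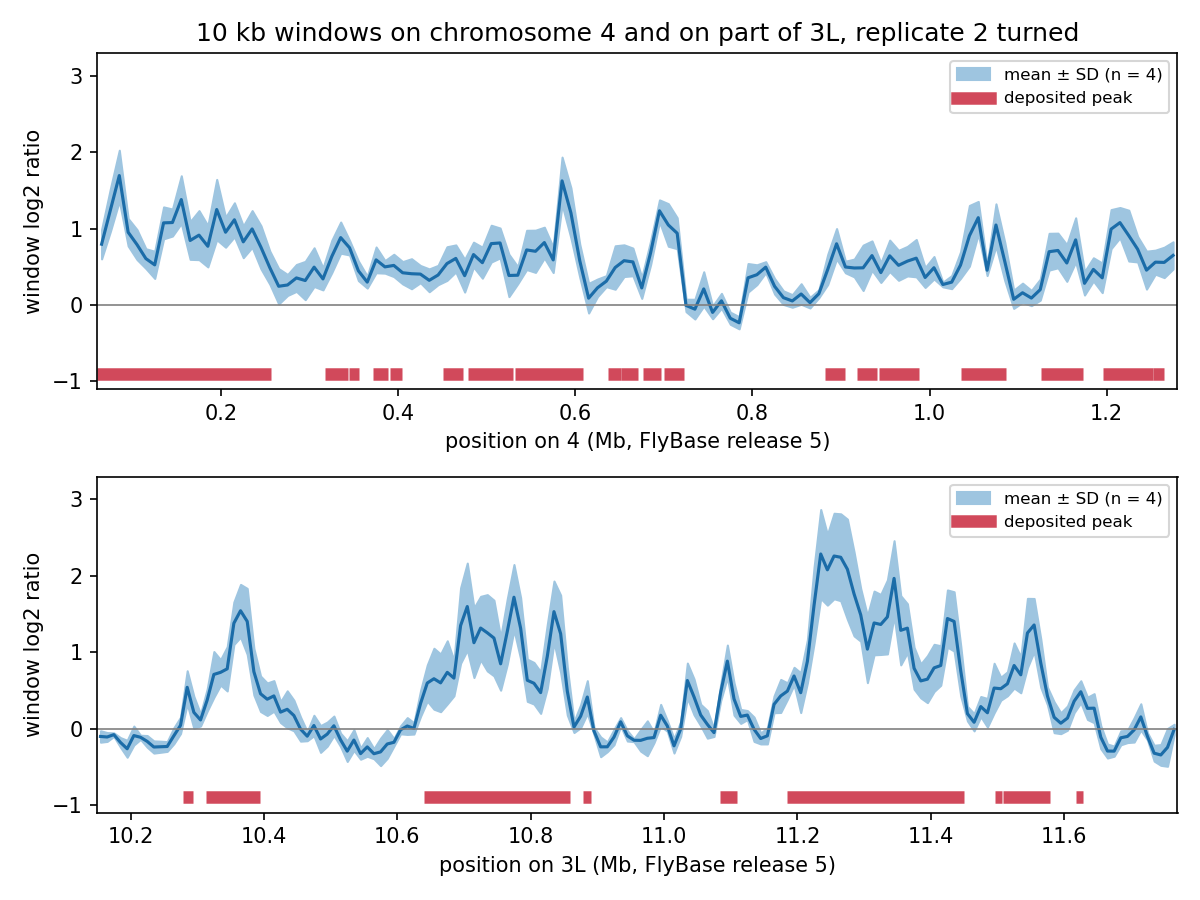
Mean log2 ratio of 10 kb windows with replicate 2 turned (vertical axis, shading 1 SD over 4 arrays) along chromosome 4 and part of 3L (horizontal axis, Mb, FlyBase release 5), with deposited peaks as bars. Peaks cover 62.1% of chromosome 4, and the widest peak of the list, 266 kb, lies on the 3L stretch.

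The YHet contigs, sequence of the Y chromosome in a female line, had fewer probes well above background than the rest of the array. Of their 158 probes, between 67.7% and 84.2% were well above background in Cy3 and between 67.7% and 79.7% in Cy5, over the 4 arrays. Their ratio with replicate 2 turned was 0.36, -0.50, 0.92 and -0.53 on replicates 1 to 4. None of the 3 YHet peaks passed limma's threshold, with adjusted p of 0.949, 0.822 and 0.991.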

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

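Of the explanations weighed here, the tests of a wrong dye record and of other sign assignments were chosen after the result was seen, as was the comparison of chromosome 4 with the autosomes and every value with replicate 2 turned. No biological explanation was tested for any of them, since the design has 1 group.

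Replicate 2 ran opposite to its dye label in its pattern of windows over most of the large arms and chromosome 4. A dye bias of single probes would not carry over to neighbouring probes, yet windows built from the odd-numbered probes of replicate 2 correlated at 0.917 with windows built from the even-numbered probes of replicates 1 and 3 after GC correction, which argues against it. With replicate 2 turned, the lowest of the 6 pairwise window correlations was 0.63 (replicates 3 and 4), and the 3 that involve replicate 2 were 0.96, 0.88 and 0.80. Over single probes, the pairs without replicate 2 correlated at 0.74 (1 and 3), 0.31 (1 and 4) and -0.008 (3 and 4). Replicates 3 and 4 thus ran together only after averaging in windows. A candidate explanation for replicate 2 is that the dyes of this array were recorded the wrong way round. The contig sets went both ways. On 2LHet, 2RHet, 3LHet and XHet replicate 2 had turned means of -0.07, -0.08, -0.03 and -0.07. These lay below 0 where the other 3 arrays were above, while as labelled all 4 arrays were above 0. Of these sets, 2LHet and XHet rest on 7 and 11 windows. On 3RHet and U replicate 2 had turned means of 0.15 and 0.16, above 0 as on the other arrays, and as labelled it lay below 0. At the centromere-proximal 1 Mb, replicate 2 turned also lay below replicates 1, 3 and 4 relative to the rest of the arm on 2L (-0.03 against 0.16, 0.04 and 0.19), 2R (-0.15 against 0.09, 0.05 and 0.18), 3L (-0.27 against -0.06, 0.06 and 0.09) and X (-0.11 against -0.04, -0.06 and 0.10). On 3R it lay within their range (-0.01 against 0.06, -0.04 and 0.09). As labelled, replicate 2 stayed outside the range of the others on 2L, 3L and X and came within it on 2R. The SD over the arrays on 2L, 2R, 3L and X was 0.10, 0.14, 0.16 and 0.09 when turned. As labelled it was 0.08, 0.06, 0.14 and 0.09, so these arm ends do not settle the orientation. Over the windows of 2LHet, 2RHet, 3LHet, 3RHet and XHet together, replicate 2 had a mean of -0.01 when turned and 0.01 as labelled. The other arrays had 0.18 ± 0.02, so either orientation lay about as far off. The turned windows of replicate 2 correlated with the mean of the other arrays at 0.84. As labelled, windows of replicate 2 correlated at -0.96, -0.88 and -0.80 with replicates 1, 3 and 4. Those arrays correlated with one another at 0.93 (1 and 3), 0.77 (1 and 4) and 0.63 (3 and 4). Over windows as a whole, the ratios of replicate 2 therefore ran against its label. All these values were looked at after the result, and the labels hold no other record of the dyes. Whether the dyes were recorded the wrong way round stays unsettled. The 4 arrays allow 8 assignments of signs. The labelled one called 0 windows and the highest of the others 6532, with replicate 2 turned. Since the labelled count is 0, all 8 reach it whatever the data, so this count says nothing for or against chance.

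Replicate 4 lay apart from the other 3 arrays in 7 of 64 quantities, where the gap to the nearest array took more than the critical share of the range, and chance gives about 1 in 20 for a single quantity. The 64 share the same 4 arrays and are not independent, so that rate cannot be set against the 7. These were the means of 2L (gap share 0.840) and X (0.848), and the peaks on 3L from 8635551 (0.864), 17892771 (0.839), 3366911 (0.852) and 7829581 (0.855), and on X from 5762981 (0.877), all with replicate 2 turned. Replicate 4 also had the smallest difference between peaks and the rest, 0.46. Its GC trend was the strongest, r = 0.27 for Cy5 over Cy3, but after GC correction the difference was 0.45 against 0.91 ± 0.09 on the other 3 arrays. Among its brightest probes by Cy5 the difference was 0.569 times that of the other arrays, which argues against dim probes as well. With replicate 2 turned, replicate 4 is the only array with Cy3 in the numerator. Its lower values therefore cannot be told apart from a dye effect, and what else remains open was not tested.

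Chromosome 4 was higher than the autosomes with replicate 2 turned. After correction for probe GC the difference was 0.52 ± 0.12, close to 0.54 before, so base composition does not account for it. A lower reference signal was tested with bounds set beforehand, and the result fell between them. Against autosomal probes of equal GC, the reference channel was -0.19 ± 0.07 log2 on chromosome 4 and the other channel 0.34 ± 0.17, above 0 on 4 of 4 arrays. Levels of different probes also differ in affinity, so these values decide nothing and the explanation stays open.

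Replicate 2 lay apart from the others in the mean at 20 to 50 kb from peak edges with replicate 2 turned (gap share 0.978), with -0.07 against values near -0.09.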

How the results depend on the processing

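Alternatives on replicate 2 turned, on chromosome 4 and on GC correction of the difference inside and outside peaks were chosen after seeing the data. As labelled, limma called 0 enriched windows, 0 depleted windows and 0 peaks under the alternatives run, except without replicate 2 (range over left-out replicates 0 to 1952 enriched, 0 to 1234 depleted and 0 to 609 peaks) and with replicate 2 turned (2979, 3553 and 623), where the change follows from the sign of that array. With replicate 2 turned, leaving out each replicate gave 1924 to 3741 enriched and 1122 to 4187 depleted windows, and 600 to 625 peaks. Windows of 5 kb gave 5255 enriched and 5695 depleted, and windows of 20 kb gave 1664 and 1927, which follows from their number. A mean of at least 0.5 left 1223 enriched windows and a mean of at most -0.5 left 6 depleted, and the better-scoring peaks gave 314 of 315. Normexp background correction gave 684 depleted windows and a chromosome 4 difference of 0.39, and the cause was not tested. With the deposited values, in units of their SD, the differences were 1.47 inside against outside peaks, 0.086 for X and 0.87 for chromosome 4. The unit differs, and the cause was not tested. As labelled, leaving out each replicate gave 0.13 to 0.77 for the difference inside against outside peaks, 0.01 to 0.05 for X and 0.11 to 0.53 for chromosome 4, within an SD that exceeds each value as labelled. No difference changed sign in the 156 alternatives to the main results, while the counts of called windows and peaks among them cannot change sign. The 12 named peaks and 6 named windows kept their direction in 162 of 162 alternatives run with replicate 2 turned. Of these, 21 moved by more than the SD. They were all 18 regions with the deposited values, whose unit differs, and 3 low windows with normexp (-0.36 to -0.23), and the cause was not tested. The named regions were picked as extremes of the same data in that orientation, so their kept direction is no independent evidence. For the share of windows touching peaks, X differed from the autosomes by 1.86 points with the better-scoring peaks and by 1.36 points with a 50% overlap, and chromosome 4 by 40.1 and 45.7 points. Gene lists and transcription starts in peaks were not run. No paired analysis was possible because there is 1 group. Low signal over background limits the YHet contigs and the U peak at 6347131 to 6360890.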

Other observations

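All values in this part were chosen after the data were seen, and those from ratios are with replicate 2 turned unless stated.

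Most runs of adjacent called windows were short, with a median of 20 kb for enriched and for depleted windows. The 2979 enriched windows made up 1162 runs, 31 of them 100 kb or longer, and the 3553 depleted windows made up 1321 runs, 32 of them 100 kb or longer. The longest enriched runs lay on chromosome 4 and 3L. They were 340 kb at 4 270001 to 610000 (0.58 ± 0.14, and 0.26 ± 0.62 as labelled), 300 kb at 3L 11160001 to 11460000 (1.21 ± 0.33, and 0.52 ± 1.31 as labelled) and 230 kb at 3L 10630001 to 10860000 (0.98 ± 0.37, and 0.42 ± 1.08 as labelled). The longest depleted runs were 190 kb at 3L 310001 to 500000 (-0.32 ± 0.09, and -0.16 ± 0.33 as labelled) and 170 kb at 3R 2730001 to 2900000 (-0.30 ± 0.11, and -0.11 ± 0.34 as labelled). With replicate 2 turned the level of chromosome 4 was not unmatched. On the large arms, 11 of 10988 overlapping stretches of 122 windows had a mean at least as high. The highest, 3L 10350001 to 11570000, had 0.60 against 0.57. Turned, replicate 2 had 0.70 on that stretch and 0.64 on chromosome 4. With its sign as labelled, chromosome 4 (0.25) was slightly the higher, and the stretches were not counted in that orientation.

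Peaks were unevenly spaced along the large arms in the deposited list, which the authors called from these arrays. The median gap between neighbours was 97.5 kb (interquartile range 29.4 to 229 kb). Entries of the list count as separate peaks however close they lie, as with 2L 8203081 to 8223589 and 2L 8223801 to 8243412. The spacing is therefore that of list entries and need not be that of origins. The coefficient of variation of the gaps was 1.25, against a mean of 1.02 (95% range 0.942 to 1.11) in 1000 random placements of the same peaks, none of which reached it (permutation p = 0.000999, the smallest they can give). The placements set each entry alone and could fall on stretches without probes. They therefore cannot tell uneven spacing of origins from split entries or from stretches where no peak could be called. The longest gap, 1528 kb at 3L 6261403 to 7789170, had a mean of -0.12 ± 0.03 (-0.07 ± 0.11 as labelled) with 44.2% of its windows depleted. The 1378 kb gap at 2L 14525421 to 15903320 had 0.008 ± 0.03 (-0.007 ± 0.03 as labelled), with 9.92% depleted and 13.0% enriched.

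The telomere-proximal 1 Mb of 3L had 40.4% of its windows touching a peak, and the centromere-proximal 1 Mb none. The telomere-proximal 1 Mb of X was below the rest of the arm by -0.10 ± 0.03 on 4 of 4 arrays, and -0.05 ± 0.11 as labelled. That of 3R was below by -0.06 ± 0.03 on 4 of 4 arrays, and -0.03 ± 0.07 as labelled. Wider peaks had higher means, with a rank correlation of 0.69 across 630 peaks, which are not independent replicates. The authors called the peak edges from these same arrays, so width and mean are not separate measures. The correlation can follow from the calling alone and is not read as a property of origins. Of the 1042 enriched windows touching no peak, 255 (24.5%) lay within 20 kb of a peak, and the mean over all 1042 was 0.30 against 0.68 for those touching a peak.

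The highest peak, U 5282551 to 5308300, held 21 of the 22 saturated Cy5 spots on U on replicate 1 and all 9 saturated Cy3 spots on U on replicate 4. The U peak at 6347131 to 6360890, which was not called, had 45.5% to 63.6% of its 11 probes well above background in Cy3.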
